A study of Mus musculus with 4 samples.

How the data were processed

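Droplet single-cell RNA sequencing with 10x Genomics 3' chemistry (v3.1) measured pancreas cells of C57Bl/6J mice with an activated Kras allele and Pdx1-Cre. Each of the 4 libraries pooled 1 male and 1 female pancreas, and the groups were normal circadian (NC) and chronic jetlag (CJ), at 5 and at 9 months. Per the labels' protocols, the organ was dissected into cold PBS after cervical dislocation, minced, digested with Collagenase P at 37° C, strained and sorted for live cells. The time of day at which the mice were killed is not in the labels. The deposited matrices hold UMI counts made with Cell Ranger 6.1.2, per the submitters' processing notes and the file headers. They list barcodes already called as cells, with at least 500 UMIs each, and 32285 genes. The genome build is not given in the sources used here, and gene coordinates were not used.

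Barcodes were kept with at least 500 detected genes and at most 15% mitochondrial UMIs, which left 7556 (NC, 5 months), 8271 (CJ, 5 months), 11168 (NC, 9 months) and 9982 (CJ, 9 months). The gene minimum removed 3598, 2480, 2536 and 1934 barcodes and the mitochondrial limit 1052, 764, 1303 and 1437, with some barcodes failing both. Doublets were called per library with Scrublet (scanpy 1.11.5; expected rate 8%, 30 components), and 151, 424, 171 and 115 were removed (2.00%, 5.13%, 1.53% and 1.15%). Counts per 10000 in each cell were log-transformed, 3000 variable genes were chosen and 2845 used after sex-linked, mitochondrial, ribosomal, haemoglobin and immunoglobulin genes were left out, and a graph of 15 neighbours on 40 principal components was weighted by shared neighbours. Leiden clustering (leidenalg 0.10.2) at resolution 1.5 gave 54 clusters. No library correction was applied, since library and group are the same here.

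Clusters were named by scoring 25 marker lists, written before the data were examined, as the mean of log2 CPM (pseudocount 20 CPM) scaled for each gene from 0 in the lowest to 1 in the highest cluster. A cluster took the name of its best list when the score reached 0.5, at least 3 markers reached 0.5, the second list scored at most 0.77 of it (0.5 for acinar, whose RNA appears in other classes too), no other list had more markers among the 10 leading genes, and it did not have both a depth under 0.333 of the library median and no own marker among those 10. Clusters without a name and with at least 100 cells were split again (resolution 1.0, 15 components, 1000 variable genes), which gave 87 groups in all. Those thresholds and the splitting were set after the clusters had been seen. Principal components for clustering and for doublet calls were computed in double precision on rounded values after first results had been seen, because single-precision runs differed between processors. A monocyte-like class appeared in some of those runs and not in the final one. Cells were called female with Xist and no Y-linked UMI (Ddx3y, Uty, Kdm5d, Eif2s3y) and male with the reverse.

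For each class and library, UMIs were summed and expressed as CPM of the class sum. Shares carry Clopper-Pearson and gene levels exact Poisson 95% intervals, with an exact conditional interval for the ratio of levels and a log-normal one for the ratio of shares. UMIs of a cell are not independent of each other, so these intervals and the floor of 3 counts used against a count of 0 cover counting error only. Log2 folds used a pseudocount of 5 CPM and genes with at least 50 UMIs in the 2 libraries together. Classes with at least 100 cells in both libraries were compared. No test across libraries was made: a comparison of 2 single libraries leaves no residual spread, and cells were not used as replicates. An additive model of regime and age over the 4 libraries, with 1 residual degree of freedom, was not run. The 4 comparisons were CJ against NC at each age and 9 against 5 months in each regime.

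Gene names follow a rule written before the data were examined. Focal classes were the first 4 with enough cells of the order ductal, fibroblast, macrophage, acinar, T cell, neutrophil, B cell and endothelial. Named were the 3 highest and 3 lowest genes per class for CJ against NC, 2 and 2 for 9 against 5 months, 4 per direction with the largest smaller fold over both ages, up to 4 members with the largest folds of each of 30 fixed lists, and any clock gene. Left out of naming were sex-linked, mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, gene models with Gm or Rik names, and genes whose CPM in another named class of either library exceeded 10 times that in the class, since their RNA can come from other cells. This last part was first read across the 2 libraries. After the names had been seen it was read within each library, the literal wording. Of 144 names, 103 were shared with the first reading, 108 with one using other classes of at least 20 cells, 67 with a factor of 3 and 52 with no such rule. A list member was called at 1.5-fold, on the scale with the pseudocount, with a ratio interval that excluded 1, and a list's median was ranked among 10000 random lists drawn from 20 expression bins.

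The median log2 fold over all genes of a class lay beyond 0.1 in B cell-like cells at 5 months (-0.14, CJ against NC) and between the CJ libraries (0.21), in acinar-like cells between ages (0.11 in NC and 0.18 in CJ) and in T cell-like cells between NC ages (-0.10). In classes whose gene levels are not reported it was -0.12 (CJ against NC at 9 months), -0.21 and -0.22 (ages in NC and in CJ) in neutrophil-like and 0.12 (ages in CJ) in mature dendritic-like cells. TMM factors (edgeR 4.0.16) moved the first 5 by 0.15, -0.21, -0.11, -0.17 and 0.11. No list median with a call, and no named gene, changed direction under TMM or with class medians set to 0. Kept cells had median depths of 16062, 14620, 9111 and 10388 UMIs and 3150, 2381, 2301 and 2544 genes.

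The procedure was tested on simulated data: counts were drawn from a Poisson distribution around the pooled profile of a class at the depth of each library, with 200 genes changed by known factors. Of genes changed 1.5-, 2- and 4-fold, the percentages called in the right direction were 13.2/69.4/92.8 (fibroblast-like), 4.92/65.8/83.3 (macrophage-like), 0/16.4/55.7 (acinar-like) and 36.4/84.5/100 (T cell-like) for CJ against NC at 5 months. They were 11.1/63.5/91.9 (fibroblast-like), 8.22/67.3/96.0 (macrophage-like), 0/32.8/71.8 (acinar-like) and 12.5/74.3/95.5 (T cell-like) for CJ against NC at 9 months, 19.2/65.1/86.4 (fibroblast-like), 6.56/69.1/85.7 (macrophage-like), 8.47/27.1/62.5 (acinar-like) and 19.0/73.0/90.5 (T cell-like) for 9 against 5 months in NC, and 9.21/63.8/87.0 (fibroblast-like), 13.0/66.7/84.8 (macrophage-like), 1.39/29.3/61.4 (acinar-like) and 31.4/82.3/97.1 (T cell-like) for 9 against 5 months in CJ. No changed gene was called in the wrong direction, ratio intervals held the true ratio in 95.2% to 96.1% of genes, and unchanged genes were called only in T cell-like cells (59 of 7415 at 5 months, 17 of 10333 in NC and 31 of 9863 in CJ). The intervals assume the Poisson counts that were simulated, so this coverage was built in. Differences between cells were not simulated, so the error rate of calls on the real counts, some held by few cells, is not known from it.

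Alternatives were looser (200 genes, 25%) and stricter (1000 genes, 10%) cell filters, doublets kept, Leiden resolutions 0.8 and 2.5 (43 and 78 clusters), female-called or male-called cells alone, shares without acinar-like cells, pseudocounts of 1 and 20 CPM, minimums of 20, 200 and 1 UMIs, TMM or median scaling, cells thinned to 3000 UMIs and other free-RNA factors. Weighting the clusters of a class alike in both libraries (at least 20 cells each) and the cell filters for male-called shares were added after the data had been seen. Analyses used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.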

Results

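Pancreas from mice carrying an activated Kras allele switched on by Pdx1-Cre, a transgene that drives recombination in the pancreatic lineage, was profiled by droplet single-cell RNA sequencing under 2 light regimes and at 2 ages. The series addresses how the cells around developing pancreatic lesions respond to chronic jetlag (CJ) in comparison with a normal circadian schedule (NC). There were 4 libraries, NC and CJ at 5 months and NC and CJ at 9 months, and each library pooled the pancreas of 1 male and 1 female. With 1 library per group no difference has a replicate check, so no test between groups is given. The intervals in parentheses are 95% intervals that cover counting error only, exact for shares and gene levels and log-normal for ratios of shares, and "higher" or "lower" describes these libraries. Gene levels are CPM of the summed UMIs of a cell class, first-named library against second, with the interval of their ratio in square brackets. Members of a gene list were called higher or lower past 1.5-fold with an interval excluding 1, medians are log2 folds over all measured members, and percentiles rank them among 10000 random lists of matched expression. The files held 159589186 UMIs in 11443 barcodes (NC, 5 months), 164248251 in 10833 (CJ, 5 months), 183658331 in 14033 (NC, 9 months) and 172426362 in 12299 (CJ, 9 months). After filtering, 7405, 7847, 10997 and 9867 cells remained in that order, with median depths of 16062, 14620, 9111 and 10388 UMIs per cell.

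The cells fell into 21 classes named from marker genes. Macrophage-like, T cell-like, fibroblast-like, acinar-like and B cell-like cells were the most numerous over the 4 libraries together. Ductal-like cells numbered only 30, 29, 57 and 65 in the order above, and tuft-like cells 2, 0, 20 and 9, so gene levels were compared in fibroblast-like, macrophage-like, acinar-like and T cell-like cells, and in B cell-like cells for gene groups. Clusters left without a name held 3.78%, 2.63%, 3.84% and 3.30% of the cells. They were mainly lymphocytes that shared markers of T cells and type 2 innate lymphoid cells, acinar-like cells rich in Reg3b, Nupr1 and Clu, and cells of low depth. The shares below were measured after enzymatic digestion and a sort for live cells, both of which can set them.

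At 5 months the CJ library held more B cell-like and acinar-like cells and fewer macrophage-like and fibroblast-like cells than the NC library. B cell-like cells made up 7.94% (7.35 to 8.56) of the CJ cells against 1.35% (1.10 to 1.64) of the NC cells, a ratio of 5.88 (4.77 to 7.24). Acinar-like cells, the source of the digestive enzymes, were 27.1% (26.1 to 28.1) against 15.2% (14.4 to 16.1). Macrophage-like cells, the largest class of both libraries, were 36.3% (35.3 to 37.4) against 44.8% (43.6 to 45.9), and fibroblast-like cells 11.4% against 14.8%, ratios of 0.811 (0.780 to 0.843) and 0.768 (0.707 to 0.834). The share ratio was 0.563 (0.494 to 0.641) for conventional dendritic-like and 0.617 (0.483 to 0.789) for neutrophil-like cells, whereas T cell-like shares (4.07% and 4.36%) could not be told apart at this depth. Plasma cell-like cells, only 19 in CJ and 42 in NC, had a ratio of 0.427 (0.248 to 0.733), which came from male-called cells (2 and 22, 0.113% against 0.912% of all male-called cells). Female-called ones numbered 14 and 9 (0.464% against 0.333%). The B cell-like gap came from male-called cells: the ratio was 14.6 among them and 0.143 among female-called cells. The conventional dendritic-like ratio (1.62, against 0.334 among male-called cells) also turned among female-called cells. T cell-like shares differed by a ratio of 0.744 in female-called and 1.46 in male-called cells. Female-called ratios were 1.05 for fibroblast-like and 0.979 for macrophage-like cells, with overlapping share intervals. Sex-called totals lack most acinar-like cells, and over all non-acinar cells the macrophage-like ratio was 0.943. Fibroblast-like shares there were 15.6% (CJ) and 17.5% (NC).

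**Figure D1:**
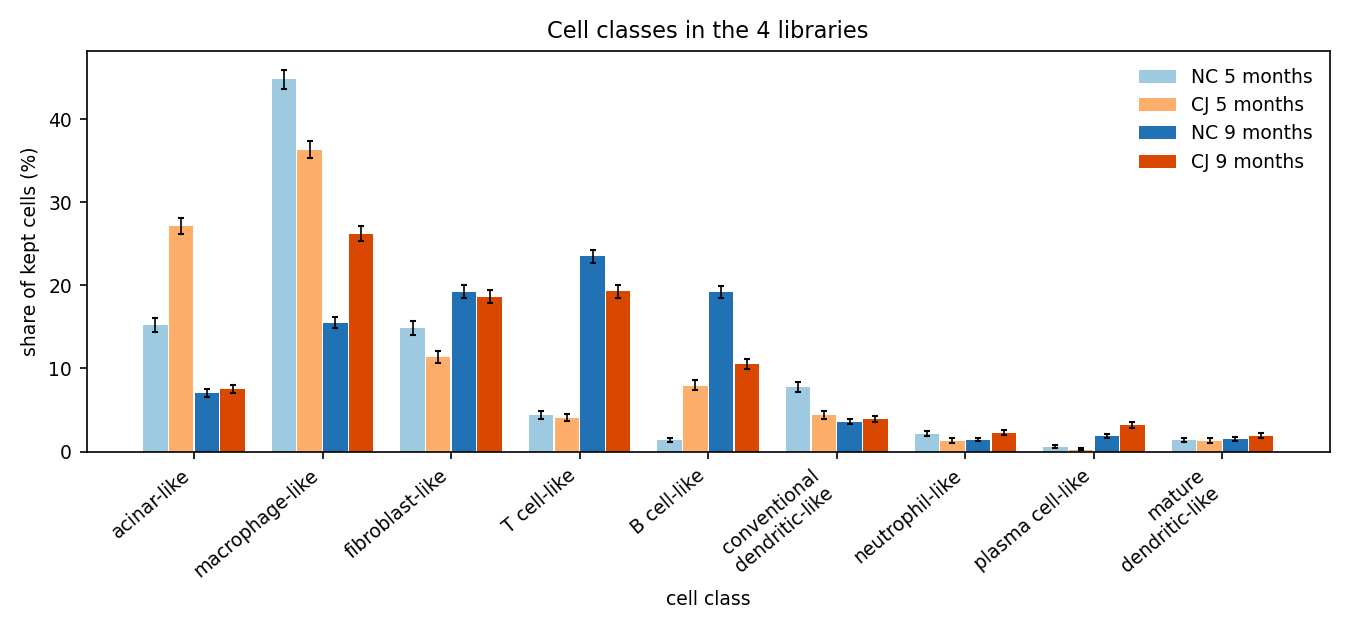
Share of kept cells in each of 9 cell classes (vertical axis, percent of kept cells) in the 4 libraries, with bars for single libraries and whiskers for exact 95% intervals of counting error. Macrophage-like cells fall from 44.8% to 15.5% between the NC libraries and from 36.3% to 26.2% between the CJ libraries, and B cell-like cells stand at 7.94% in the 5-month CJ library against 1.35% in NC.

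Genes of the molecular clock were among the largest differences of 5-month fibroblast-like cells. Dbp (ENSMUSG00000059824), a transcription factor whose rhythm is driven by clock activators, stood at 103 CPM (98.1 to 109) against 4.61 (3.75 to 5.61), 22.4-fold (18.3 to 27.8) higher in CJ. The clock repressors Per3 (88.3 against 8.33 [9.05–12.5]) and Per2 (27.1 against 1.40 [13.4–29.1]), the Dbp relatives Tef (62.8 against 10.1 [5.38–7.28]) and Hlf (52.0 against 4.10 [10.2–16.0]) and Nr1d2, which encodes REV-ERB beta (58.2 against 12.2 [4.13–5.49]), were higher as well. Genes of the opposite phase were lower: Arntl, which encodes the activator BMAL1, stood at 2.06 against 19.6 CPM [0.070–0.153], its partner Npas2 at 0.710 against 11.4 [0.030–0.117] and the D-box repressor Nfil3 at 21.1 against 56.8 [0.326–0.422]. In the list of genes driven through E-boxes and D-boxes, 6 of 12 measured members were higher and 0 lower, a median log2 fold of 1.19 (percentile 100). The list of ROR-element genes and activators had 1 of 7 members higher and 3 lower, median -0.28 (percentile 0.6). Cry1, of that list, went the other way, at 11.6 against 5.26 CPM. The E-box and D-box median ranged from 0.51 with a minimum of 20 UMIs to 1.51 in male-called cells, and was above 0 in each alternative run.

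Other fibroblast-like differences at 5 months lay in stress, contractile and antigen-presentation genes. Gsta3, a glutathione S-transferase, was 8.52-fold (7.66 to 9.49) higher in CJ, and Sult1e1 (oestrogen sulfotransferase), the imprinted zinc-finger gene Peg3 and Angptl4, an inhibitor of lipoprotein lipase, were lower (Sult1e1 at 13.4 against 79.5 [0.145–0.196], Peg3 at 22.3 against 96.6 [0.204–0.260] and Angptl4 at 31.7 against 122 [0.233–0.286]). The 3 richest cells held 36.0% of the Sult1e1 and 30.3% of the Angptl4 counts in CJ. Of the heat shock list, 7 of 12 measured members were higher and 0 lower, a median log2 fold of 0.67 (percentile 100). Hsph1 stood at 80.5 against 25.7 [2.82–3.47] and Hspb1 at 237 against 95.5 [2.35–2.62]. The unfolded protein response list had 4 of 14 members higher and 0 lower, median 0.39, led by Herpud1 (158 against 64.2 [2.30–2.63]), and the glucocorticoid list 2 of 10 members higher and 1 lower, median -0.01, with Tsc22d3 at 77.9 against 26.5 [2.65–3.25]. In the myofibroblast list, which holds contractile and matrix genes, 6 of 17 measured members were higher and 0 lower, a median log2 fold of 0.41 (percentile 100). Crlf1 stood at 33.8 against 15.0 [1.95–2.60] (3 cells held 33.4% of CJ counts) and Myl9, a myosin light chain, at 73.4 against 43.7 [1.54–1.84]. Lower in CJ were MHC class II (0 of 8 members higher and 6 lower, median -0.76; H2-Ab1 at 98.7 against 186 [0.498–0.563]) and the overlapping antigen-presenting fibroblast list (0 of 10 members higher and 7 lower, median -0.76). MHC class II RNA was lower in T cell-like cells as well (median -0.93), and macrophage-like cells, a main source of it, were 36.3% of the CJ and 44.8% of the NC cells. Called doublets removed before this were 5.13% of the CJ and 2.00% of the NC cells. The antigen-presenting fibroblast median between the CJ ages turned direction when called doublets were kept. Lower members without higher ones were found among inflammatory fibroblast genes (0 of 17 members higher and 3 lower, median -0.31; Il6 at 128 against 209 [0.581–0.649]), collagens and matrix (0 of 21 members higher and 4 lower, median -0.22; Eln, elastin, at 109 against 234 [0.439–0.492]) and inflammatory cytokines (0 of 12 members higher and 4 lower, median -0.41). The largest cluster of the class was 24 (27.9%) in NC and 16 (36.8%) in CJ, both rich in Dcn and Clec3b. With clusters weighted alike the medians were 0.05 for myofibroblast, -0.11 for inflammatory fibroblast and -0.18 for cytokine genes. Digestive enzyme RNA, which fibroblasts do not make, was also higher in the CJ cells (median 0.31), but lower with clusters weighted alike (-0.39).

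Macrophage-like cells at 5 months had Dbp, Per2, Per3 and Tef higher in CJ, at smaller folds than fibroblast-like cells. Dbp stood at 36.6 against 6.05 CPM [5.38–6.79], Per3 at 18.7 against 4.86 [3.36–4.41] and Tef at 19.5 against 7.52 [2.31–2.91], and in the E-box and D-box list 4 of 12 measured members were higher and 0 lower, a median log2 fold of 0.37 (percentile 100). This median lay between 0.14 with a pseudocount of 20 CPM and 0.64 with cells thinned to 3000 UMIs. The ROR-element list had a median of -0.29 (percentile 1.0), although its member Cry1 was higher at 9.52 against 3.71 CPM. Hsph1, a co-chaperone, was 3.14-fold (2.94 to 3.35) higher and the heat shock list had 6 of 12 members higher and 0 lower, median 0.55. Chil3, a chitinase-like protein of activated macrophages, and the ficolin Fcna were lower (Chil3 at 13.9 against 52.5 [0.243–0.288] and Fcna at 48.7 against 153 [0.304–0.333]). Of the genes of alternative activation and lipid handling, 0 of 15 measured members were higher and 3 lower, a median log2 fold of -0.04 (percentile 38.0), with Folr2 at 203 against 385 [0.516–0.542] and the lipid receptor Cd36 at 78.1 against 125 [0.601–0.651]. Proliferation genes had a median of -0.29 (percentile 0) with no member past 1.5-fold, and immediate early and dissociation genes one of -0.29 (percentile 0). Insulin (Ins2) was lower at 0.633 against 10.6 CPM [0.040–0.086], but 3 cells held 92.5% of its NC counts. Cluster 5 (23.9%), rich in Ccl8 and Folr2, was the largest of the class in NC and cluster 8 (21.4%), rich in Retnla and Lyz1, in CJ. Digestive enzyme RNA was higher in the CJ macrophage-like cells by a median of 0.82, with 18 of 19 members past 1.5-fold.

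In acinar-like cells the 5-month CJ library had more chaperone and endoplasmic reticulum stress transcripts and less Mt1. Of the unfolded protein response list, 4 of 15 measured members were higher and 0 lower, a median log2 fold of 0.50 (percentile 100); Herpud1 stood at 73.0 against 27.7 CPM [2.46–2.82], Chac1 at 11.5 against 2.55 [3.64–5.64] and the chaperone Hspa5 at 296 against 160.2 [1.79–1.90]. Heat shock genes had 6 of 12 members higher and 0 lower, median 0.45. Cth (cystathionine gamma-lyase) and the hormone Fgf21 were higher (Cth at 15.5 against 5.82 [2.29–3.09] and Fgf21 at 6.32 against 1.38 [3.42–6.23]), as was the trypsinogen Prss1 (7.95 against 1.83 [3.37–5.66]), whose reads may be shared with Prss3 (3 cells held 39.1% of its CJ counts). Mt1, which encodes a metallothionein, was lower at 423 against 1683 CPM [0.248–0.255], as were Sostdc1, a BMP and Wnt antagonist (6.08 against 22.001 [0.245–0.312]), and Smim38 (9.65 against 24.3 [0.358–0.441]). The regeneration and injury list had 0 of 9 members higher and 1 lower, median -0.33, with Reg2 at 9514 against 15518 [0.611–0.615]. Metaplasia genes had 0 of 11 members higher and 1 lower, median -0.20, with Lcn2 (lipocalin) at 2.19 against 11.8 [0.152–0.225]. MHC class I had 0 of 13 members higher and 1 lower, median -0.28, with B2m at 20.4 against 45.1 [0.419–0.485]. Mitochondrial transcripts had a median of -0.41 (percentile 0). The digestive enzymes themselves differed little (0 of 19 members higher and 0 lower, median 0.05), and E-box and D-box clock genes had 2 of 7 members higher and 0 lower, median 0.44. The largest cluster of the class was 10 (38.1%), rich in Tff2, in NC and 4 (49.0%), rich in Cela1, in CJ.

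T cell-like cells of the 5-month CJ library had more cytotoxicity transcripts and more Trdc. In the cytotoxicity list 5 of 11 measured members were higher and 0 lower, a median log2 fold of 0.39 (percentile 100), with the granzymes Gzmk (43.3 against 11.1 CPM [2.62–5.99]; 3 cells held 25.9% of CJ counts), Gzma (61.8 against 22.1 [2.08–3.79]) and Gzmb (42.5 against 14.5 [2.03–4.28]). Trdc, the constant region of the T cell receptor delta chain, was 2.75-fold (2.45 to 3.095) higher and the cytokine Il17a stood at 143 against 41.2 [2.82–4.31], though 3 cells held 48.9% of its CJ and 56.3% of its NC counts. The rest of the type 17 list did not follow (1 of 7 members higher and 1 lower, median -0.17). The interferon list had 4 of 15 members higher and 0 lower, median 0.21. Lower were the protease Furin (34.8 against 92.0 [0.294–0.482]), Trerf1 (9.66 against 29.4 [0.202–0.518]), the chemokine receptor Ccr4 (17.007 against 43.2 [0.272–0.559]) and MHC class II (median -0.93). Naive T cell, regulatory T cell and inhibitory receptor genes had medians of -0.26 (percentile 0.7), -0.34 (percentile 0.4) and -0.10 (percentile 46.6). Clock genes of the E-box and D-box list had 0 of 5 members higher and 1 lower, median -0.13. Digestive enzyme RNA was higher by a median of 0.70. In B cell-like cells, proliferation genes were lower in CJ (0 of 17 members higher and 16 lower, median -1.43), with Top2a at 32.3 against 242 [0.105–0.169], beside an overall shift of -0.14 and only 100 cells in NC. The cycling clusters held just 4 of these and 4 of the 623 CJ cells, so the median, -0.23 with clusters weighted alike, rests on few cells. The clusters that fill the class differed too, with 68.0% and 94.2% in cluster 6, the largest.

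At 9 months the direction of the B cell-like and macrophage-like differences was the opposite of that at 5 months. B cell-like cells were 10.5% (9.94 to 11.2) of the CJ and 19.2% (18.4 to 19.9) of the NC library, a ratio of 0.550 (0.514 to 0.590), and macrophage-like cells 26.2% (25.4 to 27.1) against 15.5% (14.9 to 16.2), a ratio of 1.69 (1.60 to 1.78). Neutrophil-like (1.54, 1.26 to 1.89), plasma cell-like (1.75, 1.47 to 2.08) and mature dendritic-like cells (1.27, 1.03 to 1.56) had larger shares in CJ, and T cell-like cells a smaller one (19.3% against 23.5%, ratio 0.822, 0.780 to 0.866). The neutrophil-like ratio rests on immature cells, without which the shares were 1.34% and 1.37%. Fibroblast-like shares were 18.6% and 19.2%, and acinar-like shares 7.52% and 6.99%, with ratios of 0.970 (0.917 to 1.03) and 1.08 (0.976 to 1.19). The fibroblast-like ratio was 0.590 in female-called and 1.30 in male-called cells. The ratio for T cell-like cells was 1.12 in female-called and 0.514 in male-called cells, and that for B cell-like cells 0.348 in male-called cells. Female-called B cell-like shares were smaller in CJ at both ages (14.9% against 18.4% here, 0.232% against 1.63% at 5 months). Among sex-called cells the turn between ages was thus in male-called ones alone. For acinar-like cells the ratio was 0.692 under the looser cell filter, 0.699 in female-called and 1.57 in male-called cells, and for neutrophil-like cells 0.901 in male-called cells. Cluster 31 held 116 of 151 (NC) and 61 of 91 (CJ) female-called acinar-like cells, so no direction is read from the 0.699.

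Clock genes led the higher side of the fibroblast-like comparison at 9 months, and Dlk1 the lower side. Dbp stood at 55.9 against 8.41 CPM [5.92–7.48], Per3 at 53.9 against 9.07 [5.30–6.66], Per2 at 21.1 against 1.39 [11.6–20.3] and Tef at 41.5 against 11.4 [3.26–4.04]. Npas2 was lower at 2.24 against 15.5 [0.111–0.186] and Arntl at 6.03 against 21.4 [0.239–0.332]. In the E-box and D-box list 7 of 13 measured members were higher and 1 lower, a median log2 fold of 0.65 (percentile 100). The ROR-element list had 1 of 7 members higher and 2 lower, median -0.08, and its member Cry1 stood at 11.6 against 5.41 CPM. Lpl, lipoprotein lipase, was lower at 127 against 491 CPM [0.249–0.267] and so was Dlk1, a preadipocyte marker, at 0.395 against 21.2 [0.010–0.033] (3 cells held 28.1% of NC counts). Several chaperone genes were higher in CJ. The heat shock list had 4 of 12 members higher and 0 lower, median 0.34, with the small heat shock protein Hspb1 at 1114 against 478 [2.29–2.37], and the unfolded protein response list 4 of 14 members higher and 0 lower, median 0.34, with Hspa5 at 1772 against 937 [1.87–1.92]. Inflammatory cytokines had 5 of 17 members higher and 0 lower, median 0.43, led by Ptgs2, the inducible cyclooxygenase (505 against 251 [1.97–2.07]). The glucocorticoid list had a median of 0.35 (percentile 100) with Tsc22d3 at 84.3 against 42.5 [1.87–2.11], and TGF-beta response genes 2 of 11 members higher and 0 lower, median 0.26, with Ccn2 at 296 against 151 [1.90–2.03]. Myofibroblast and matrix genes differed little (medians 0.03 and -0.05). Digestive enzyme RNA in these cells was lower in CJ (median -0.42). Cluster 0 (44.7%), rich in Col1a1 and Sfrp1, was the largest in NC as in CJ (53.3%). The E-box and D-box median was 1.02 with thinned cells and 0.43 with a pseudocount of 20 CPM.

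**Figure D2:**
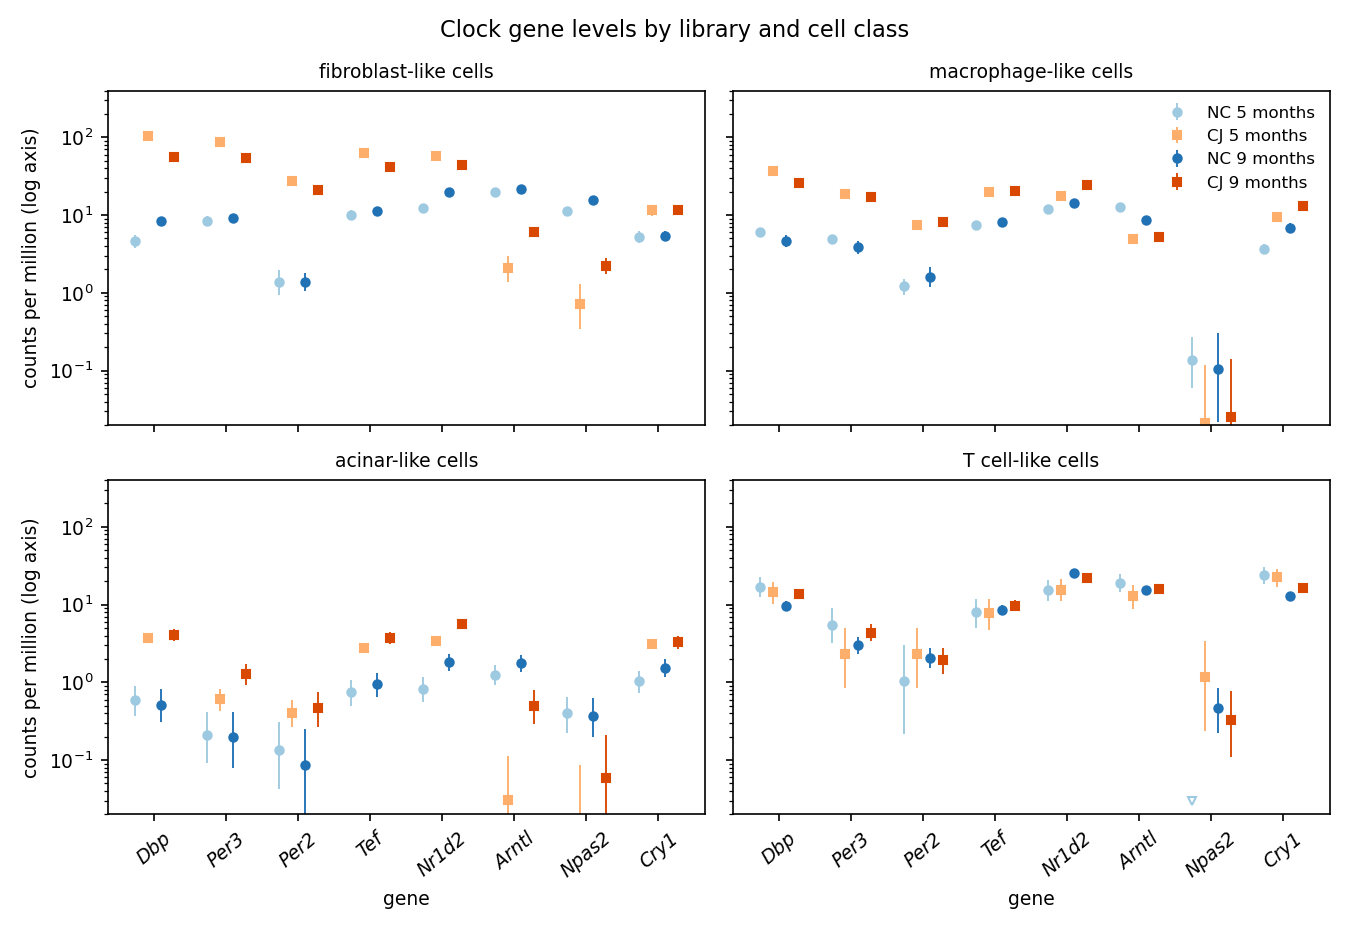
Levels of 8 clock genes (horizontal axis) in CPM on a log axis, with 1 panel each for fibroblast-like, macrophage-like, acinar-like and T cell-like cells, 1 symbol per library, and whiskers for exact 95% Poisson intervals. An open downward triangle marks a count of 0 at a fixed height that is not a level. For Npas2 in T cell-like cells of NC at 5 months, which had that count, the interval reaches 1.28 CPM. In fibroblast-like cells Dbp lies at 103 and 55.9 CPM in the CJ libraries against 4.61 and 8.41 CPM in the NC libraries, and Arntl the other way round.

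Among 9-month macrophage-like cells, CJ had more Dbp (25.8 against 4.70 CPM [4.58–6.63]) and Tef (20.5 against 8.06 [2.19–2.95]), and in the E-box and D-box list 5 of 12 measured members were higher and 0 lower, a median log2 fold of 0.51 (percentile 100). This median was 0.10 in female-called and 0.78 in male-called cells. Of the alternative activation and lipid list, 3 of 15 measured members were higher and 0 lower, a median log2 fold of 0.20 (percentile 99.98), with Retnla at 2118 against 1089.5 [1.92–1.97], the hyaluronan receptor Lyve1 at 72.2 against 39.8 [1.69–1.95] and the scavenger receptor Cd163 at 63.0 against 39.8 [1.47–1.70]. The neutrophil granule proteases Ctsg (57.7 against 0.105 [187–2662]) and Prtn3 (112 against 14.7 [6.93–8.49]) were higher in CJ, but 16 cells held all 2291 Ctsg counts and 3 cells held 83.8% of these and 65.5% of the Prtn3 counts. In male-called cells Prtn3 was lower in CJ (log2 fold -0.47). Hist1h4d, a histone gene with near-identical copies, the phospholipase Pla2g2d and the growth factor Nrg1 were lower (Hist1h4d at 21.2 against 44.8 [0.434–0.517], Pla2g2d at 7.86 against 18.4 [0.369–0.491] and Nrg1 at 68.6 against 123 [0.532–0.588]), and 3 cells held 43.2% of the NC and 36.5% of the CJ Pla2g2d counts. Heat shock genes had 1 of 12 members higher and 0 lower, median 0.28, interferon genes 2 of 21 members higher and 1 lower, median 0.28 and the Nrf2 list 1 of 8 members higher and 0 lower, median 0.14, with the haem oxygenase Hmox1 at 205 against 128 [1.54–1.67]. Inflammatory cytokines and MHC class II differed little (medians 0.04 and 0.10). All 19 measured digestive enzymes were lower in CJ (median -1.38).

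Acinar-like cells at 9 months had Uba52, a ubiquitin and ribosomal protein fusion, at 277 against 82.2 CPM [3.23–3.52], Gstp1, a glutathione S-transferase, at 234 against 68.1 [3.28–3.59] and Dym at 115 against 41.9 [2.58–2.91]. Uba52 and Gstp1 have near-identical copies and were higher in T cell-like cells too (1177 against 428 [2.68–2.82] and 105 against 39.2 [2.46–2.92]). The unfolded protein response list was higher (7 of 15 members higher and 0 lower, median 0.53), with Atf5 at 81.5 against 43.2 [1.77–2.01] and Hsp90b1 at 219 against 121 [1.74–1.88]. Metaplasia genes had 3 of 12 members higher and 1 lower, median 0.02, with Lcn2 at 43.2 against 19.3 [2.04–2.45] and Spp1 (osteopontin) at 11.6 against 3.94 [2.41–3.58]. The digestive enzymes had 0 of 19 members higher and 2 lower, median -0.14. The amylase Amy2a5 stood at 617 against 1139 [0.533–0.551] and the lipase Pnlip at 15644 against 26460.5 [0.589–0.593]. Sostdc1 (7.44 against 18.3 [0.351–0.471]) and the neuropeptide galanin, Gal (15.3 against 29.8 [0.462–0.571]), were lower, as were medians of MHC class I (-0.34, percentile 0) and mitochondrial transcripts (-0.38, percentile 0). Clock genes had 2 of 7 members higher and 1 lower, median 0.52.

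T cell-like cells at 9 months differed by interferon and immediate early genes. In the interferon list 7 of 20 measured members were higher and 0 lower, a median log2 fold of 0.46 (percentile 100), with Ifit1 at 27.9 against 12.014 CPM [1.98–2.72] and Ifi47 at 115 against 64.5 [1.66–1.91]. Immediate early and dissociation genes were lower (0 of 14 members higher and 5 lower, median -0.51), with Fosb at 67.2 against 194 [0.324–0.372] and Jun at 335 against 611 [0.531–0.566]. Il17a was lower at 64.7 against 128 [0.471–0.545], although it was higher in male-called cells (log2 fold 0.56), and 3 cells held 26.0% of its CJ counts. Il22 and Il17f were lower with it (1.32 against 5.68 [0.138–0.376] and 4.37 against 9.80 [0.333–0.591]). The histone genes Hist1h2ap (154 against 74.8 [1.94–2.20]) and Hist1h4d (29.9 against 72.1 [0.372–0.460]), which have near-identical copies, went opposite ways (3 cells held 26.6% of the CJ Hist1h2ap counts), and Rab4a was lower (6.96 against 17.1 [0.324–0.505]). Cytotoxicity genes had 2 of 12 members higher and 0 lower, median 0.12, naive T cell genes a median of -0.04 (percentile 8.2) and E-box and D-box clock genes one of 0.03 (percentile 22.2). In B cell-like cells the proliferation genes were higher in CJ (14 of 19 members higher and 0 lower, median 1.14), with Ube2c at 138 against 22.1 [5.50–7.06]. Cluster 1, the largest in both, held 74.6% of the class in NC and 47.3% in CJ, and with clusters weighted alike the median was 0.06. The cycling clusters held 39 and 37 cells, and of the 35 sex-called ones in CJ 33 were female-called. Digestive enzyme RNA was lower in the CJ T cell-like cells (median -0.81). Cluster 13 (23.8%), rich in Lef1 and Tcf7, was the largest of the class in NC and cluster 12 (23.1%), rich in Ikzf2 and Ctla4, in CJ.

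Some genes differed in the same direction between CJ and NC at both ages, and log2 folds at 5 and 9 months are given for them. In fibroblast-like cells Dbp (3.50 and 2.18), Per3 (2.81 and 2.06), Tef (2.17 and 1.499) and Cys1 (2.08 and 1.27), which encodes the cilium protein cystin, were higher. On the lower side were Npas2 (-1.52 and -1.498), Lpl (-1.24 and -1.91), the matrix protein gene Spon2 (-1.08 and -1.19) and the collagen Col5a3 (-1.02 and -1.20). Macrophage-like cells had more Dbp (1.91 and 1.67), Tef (0.97 and 0.96), the dynein light chain Dynll1 (0.85 and 0.74) and Tspan4 (0.68 and 0.63). They had less Pla2g2d (-0.57 and -0.87), Rnaset2a (-0.58 and -0.51) and of the mitotic genes Nusap1 (-0.56 and -0.70) and Prc1 (-0.54 and -0.59), the last of which was higher in female-called cells at 9 months (0.30). In acinar-like cells spermidine synthase, Srm (0.72 and 0.92), Dym (0.70 and 1.35), the stress-inducible secreted factor Manf (0.66 and 0.70) and Adm2 (0.66 and 0.71) were higher, and Sostdc1 (-1.28 and -0.90), Hsbp1l1 (-0.84 and -0.67), Lcmt1 (-0.64 and -0.63) and Casp9 (-0.48 and -0.65) lower. T cell-like cells had more Ifit3 (0.85 and 0.78), Adgrg5 (0.76 and 0.74), Tcrg-C1 (0.92 and 0.55) and Ifi47 (0.54 and 0.79), and 3 cells held 31.6% of the 5-month CJ counts of Ifit3. Lower there were Map3k14 (-0.53 and -0.51), which encodes the kinase NIK, Fosl2 (-0.64 and -0.50), the histone demethylase gene Kdm6b (-0.84 and -0.49) and Neurl3 (-0.48 and -0.48).

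Between 5 and 9 months in NC, lymphocytes took a larger and macrophage-like cells a smaller share. B cell-like cells made up 19.2% at 9 and 1.35% at 5 months (ratio 14.2, 11.6 to 17.3), T cell-like cells 23.5% and 4.36% (ratio 5.38, 4.81 to 6.02), and macrophage-like cells 15.5% and 44.8% (ratio 0.347, 0.330 to 0.365). Acinar-like (0.460, 0.421 to 0.501) and conventional dendritic-like cells (0.464, 0.410 to 0.526) had smaller shares at 9 months, and fibroblast-like (1.30, 1.21 to 1.39), plasma cell-like (3.24, 2.33 to 4.51) and tuft-like cells (6.73, 1.57 to 28.8) larger ones. The macrophage-like ratio was 0.233 in female-called cells. The plasma cell-like difference came from female-called cells (3.11% against 0.333%), whereas male-called shares were 0.902% and 0.912%.

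Fibroblast-like cells of the 9-month NC library carried more contractile, TGF-beta and cytokine transcripts than those at 5 months. In the myofibroblast list 13 of 17 measured members were higher and 0 lower, a median log2 fold of 0.94 (percentile 100), with the collagen Col8a1 at 282 against 85.7 CPM [3.13–3.46] and Igfbp3 at 318 against 90.4 [3.36–3.69]. TGF-beta response genes had 10 of 11 members higher and 0 lower, median 0.95, with Ltbp2 at 69.5 against 12.5 [4.89–6.31]. Inflammatory cytokines had 10 of 16 members higher and 0 lower, median 0.79, with the monocyte attractant Ccl2 at 679 against 151 [4.34–4.67], and Kras and MAPK output genes 6 of 15 members higher and 0 lower, median 0.41. Sult1e1 and the acute phase gene Saa3 were lower (Sult1e1 at 14.4 against 79.5 [0.164–0.198] and Saa3 at 112 against 471 [0.230–0.247]), with 27.5% of the 9-month Sult1e1 and 32.0% of the 5-month Saa3 counts in 3 cells. Interferon genes had 1 of 21 members higher and 8 lower, median -0.49. Crlf1 stood at 84.0 against 15.0 [4.99–6.28] and Igfbp2 at 20.1 against 0.047 [77.4–17108], where 3 cells held 29.7% of the 5-month Crlf1 and 67.1% of the 9-month Igfbp2 counts. The largest cluster changed from 24 (27.9%) to 0 (44.7%), and with clusters weighted alike the myofibroblast median was 0.15.

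NC macrophage-like cells at 9 months had higher cytokine genes. In the inflammatory cytokine list 13 of 17 measured members were higher and 0 lower, a median log2 fold of 1.41 (percentile 100), with Il1a at 162 against 41.0 CPM [3.76–4.15] and Il10 at 78.5 against 19.3 [3.79–4.38]. With clusters weighted alike the median was 0.79. The growth factors Nrg1 (neuregulin) and Vegfa were higher (Nrg1 at 123 against 12.2 [9.28–10.9] and Vegfa at 204 against 27.2 [7.11–7.95]), glycolysis and hypoxia genes had 5 of 19 members higher and 0 lower, median 0.16, and the Kras and MAPK list 4 of 12 members higher and 0 lower, median 0.21, with the EGF receptor ligand Areg at 186 against 58.8 [3.04–3.31]. The lectin Cd209f and the lysozyme Lyz1 were lower (Cd209f at 24.5 against 198 [0.115–0.134] and Lyz1 at 55.0 against 340.2 [0.154–0.170]), as were Retnla (1089.5 against 5426 [0.198–0.203]) and Folr2 (93.8 against 385 [0.234–0.254]) of the alternative activation list (2 of 15 members higher and 5 lower, median -0.08). The interferon list was mixed (2 of 21 members higher and 7 lower, median -0.52), with Cxcl9 at 86.2 against 11.8 [6.71–7.96]. Cluster 5 (23.9%) was the largest at 5 and cluster 11 (27.6%), rich in Arg1, Mmp12 and Cxcl2, at 9 months. Digestive enzyme RNA had a median of 0.30.

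In NC acinar-like cells at 9 months, MHC class I genes were higher (9 of 14 members higher and 0 lower, median 0.95), with H2-D1 at 93.2 against 38.3 CPM [2.29–2.59], but the median was 0.051 with clusters weighted alike. Also higher were immediate early (8 of 14 members higher and 0 lower, median 0.65) and heat shock genes (6 of 12 members higher and 0 lower, median 0.68). The trypsinogens Prss1 and Prss3, near-identical copies, were higher (Prss1 at 40.2 against 1.83 [17.2–28.4] and Prss3 at 974 against 173 [5.48–5.78]; 3 cells held 27.7% of the 9-month Prss1 counts) and the metallothioneins Mt1 and Mt2 lower (Mt1 at 649.7 against 1683 [0.380–0.392] and Mt2 at 76.1 against 209.7 [0.347–0.379]), beside a median shift of 0.11 over all measured genes. The largest cluster was 10 (38.1%) at 5 and 9 (45.1%), rich in Reg3b, at 9 months. T cell-like cells at 9 months had more naive genes (7 of 8 members higher and 1 lower, median 0.89; the lymph node homing receptor Ccr7 at 301 against 52.9 [4.84–6.72]) and fewer type 17 genes (3 of 9 members higher and 6 lower, median -0.88; Rorc at 6.24 against 28.4 [0.166–0.293]), beside an overall shift of -0.10. The largest cluster was 20 (31.6%) at 5 and 13 (23.8%), rich in Lef1 and Tcf7, at 9 months. With clusters weighted alike the naive median was 0.34 and the type 17 median 0.21. The near-identical heat shock genes Hspa1a and Hspa1b stood at 555 against 117 [4.26–5.30] and 758 against 158 [4.37–5.28], S100a4 at 330.1 against 1545 [0.206–0.222] and Krt83 at 18.4 against 85.4 [0.183–0.253]. Inhibitory receptor and regulatory T cell lists had medians of 0.27 (percentile 99.6) and -0.18 (percentile 22.4).

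Between the CJ libraries, T cell-like cells were 19.3% at 9 and 4.07% at 5 months (ratio 4.74, 4.23 to 5.32), plasma cell-like cells differed by a ratio of 13.3 (8.36 to 21.1) and fibroblast-like cells by 1.64 (1.52 to 1.76), while acinar-like (0.278, 0.257 to 0.300) and macrophage-like shares (0.722, 0.691 to 0.754) were smaller at 9 months. The B cell-like ratio was 1.33 (1.21 to 1.46), with 64.3 in female-called and 0.369 in male-called cells. The ratio in female-called cells was 0.707 for fibroblast-like cells, and that of mature dendritic-like cells (1.47, 1.16 to 1.87) was 0.889 in male-called cells. Fibroblast-like cells at 9 months had more TGF-beta (10 of 11 members higher and 0 lower, median 1.33), cytokine (15 of 16 members higher and 0 lower, median 1.63) and immediate early transcripts (9 of 14 members higher and 0 lower, median 0.82), with Ccl2 at 1101 against 176 CPM [6.01–6.53], Cxcl2 at 264 against 38.7 [6.26–7.46] and Serpine1 at 218 against 62.9 [3.24–3.73]. Myofibroblast genes had 10 of 17 members higher and 0 lower, median 0.77, and a median of -0.01 with clusters weighted alike. The largest cluster was 16 (36.8%) at 5 and 0 (53.3%) at 9 months. Antigen-presenting fibroblast genes were higher (median 0.86), but lower with called doublets kept (-0.38). Ifrd1 and the protease inhibitor A2m were higher (Ifrd1 at 474 against 79.1 [5.63–6.37] and A2m at 52.2 against 7.03 [6.06–9.19]), and Dlk1 and the convertase Pcsk6 lower (Dlk1 at 0.395 against 45.9 [0.004–0.015] and Pcsk6 at 17.8 against 103 [0.157–0.191]). At 5 months 3 cells held 27.5% of the Dlk1 and 34.3% of the A2m counts.

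CJ macrophage-like cells at 9 months had higher cytokine genes (16 of 17 members higher and 0 lower, median 1.18), with Il10 at 105 against 9.58 CPM [9.92–12.1]. The median was 0.35 in female-called cells and 0.71 with clusters weighted alike. Cluster 8 (21.4%), rich in Retnla and Lyz1, was the largest of the class at 5 months (6.57% at 9), and cluster 11 (19.985%), rich in Arg1 and Cxcl2, at 9 months (4.91% at 5). Vegfa (153 against 25.1 [5.74–6.50]) led the glycolysis and hypoxia list (5 of 19 members higher and 0 lower, median 0.27), and the Nrf2 list had 3 of 8 members higher and 0 lower, median 0.33, with the cystine transporter Slc7a11 at 43.8 against 20.3 [2.00–2.34]. Lyz1 and the calcium channel gene Cacna1a were lower (Lyz1 at 111 against 419 [0.257–0.274] and Cacna1a at 22.9 against 78.6 [0.271–0.313]; log2 folds -0.91 and -1.26 with clusters weighted alike), and Ctsg and Prtn3 higher on the few cells given above (Ctsg at 57.7 against 0.063 [311–4422] and Prtn3 at 112 against 7.89 [12.8–15.9]). Nuclear genes of oxidative phosphorylation had no member past 1.5-fold in any of the 4 focal classes and 4 comparisons, with medians here of 0.05 (percentile 72.1) in macrophage-like and 0.27 (percentile 39.6) in acinar-like cells.

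In the CJ libraries, acinar-like cells at 9 months had more MHC class I (9 of 14 members higher and 0 lower, median 0.74; B2m at 81.2 against 20.4 [3.74–4.26]) and some more metaplasia transcripts (4 of 12 members higher and 0 lower, median 0.43; Lcn2 at 43.2 against 2.19 [16.6–23.7], Agr2 at 41.6 against 15.4 [2.49–2.93]), beside a shift of 0.18 over all genes. The largest cluster was 4 (49.0%), rich in Cela1, at 5 and 9 (54.3%), rich in Reg3b, at 9 months. Prss3 and Fetub were higher (Prss3 at 1926 against 268 [7.06–7.30] and Fetub at 112 against 15.5 [6.75–7.77]), and Lars2, Gal and Pnlip lower (Lars2 at 241 against 905 [0.261–0.273], Gal at 15.3 against 60.5 [0.231–0.277] and Pnlip at 15644 against 43948 [0.355–0.357]). Immediate early genes were higher (11 of 14 members higher and 0 lower, median 0.87), but not in female-called cells (median -0.21). With clusters weighted alike the medians were -0.02 for MHC class I, 0.082 for metaplasia and 0.52 for immediate early genes, and the log2 folds 1.34 for Prss3, -1.06 for Lars2 and -0.81 for Gal. These are smaller in size. Clusters were built from the same expression values, so which clusters fill the class and a change within cells cannot be told apart. T cell-like cells, with 20 (29.8%) the largest cluster at 5 and 12 (23.1%) at 9 months, had more naive (7 of 8 members higher and 0 lower, median 1.01; 0.59 with clusters weighted alike) and fewer type 17 transcripts (1 of 8 members higher and 7 lower, median -1.06; 0.09 with clusters weighted alike). Their proliferation genes were lower (1 of 19 members higher and 11 lower, median -0.63) but not with clusters weighted alike (median 0.07). In B cell-like cells, whose largest cluster was 6 at 5 and 1 at 9 months, the proliferation medians between ages were -1.14 in NC (0.33 with clusters weighted alike) and 1.58 in CJ (-0.34 in male-called cells). S100a4 and the scavenger receptor gene Cd163l1 were lower (S100a4 at 247 against 1005 [0.234–0.258] and Cd163l1 at 22.988 against 96.6 [0.202–0.281]), although Cd163l1 was higher in male-called cells (log2 fold 0.28). Hspa1b and Sostdc1 were higher (Hspa1b at 699 against 217 [2.96–3.51] and Sostdc1 at 14.8 against 0.773 [5.23–159]), with 27.8% of the 9-month Sostdc1 counts in 3 cells. Digestive enzyme RNA was lower at 9 months in macrophage-like and T cell-like cells (medians -1.99 and -1.79).

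Cells could be traced to 1 of the animals of each pool where they held Xist or Y-linked transcripts. Xist-positive, female-called cells made up 36.5% and Y-positive, male-called cells 32.6% of NC cells at 5 months, 38.4% and 22.6% of CJ cells at 5 months, 40.6% and 35.3% in NC at 9 months, and 39.0% and 37.4% in CJ at 9 months. B cell-like cells were male-called in 42.1%, 98.0%, 49.1% and 31.4% of calls in the order NC and CJ at 5 months, NC and CJ at 9 months. For T cell-like cells these shares were 33.8%, 39.8%, 41.6% and 26.5%, for macrophage-like cells 42.3%, 30.6%, 57.0% and 61.5%, and for fibroblast-like cells 42.8%, 25.8%, 41.5% and 63.3%. Acinar-like cells held neither kind of transcript in 86.8%, 91.3%, 65.4% and 66.0% of cells, so no direction is read from their sex-called shares at 5 months or between ages. At 9 months that rate was alike, but cluster 31 held most female-called cells of the class, so no direction is read from those either. Macrophage-like cells were 57.7% of female-called and 43.2% of male-called cells in the 5-month CJ library. Each sex is 1 animal in a library, so a difference between them can belong to the animal as much as to its sex.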

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

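All tests weighed here were chosen after the results had been seen. The differences between groups listed first were not tested, since each group is 1 library. They are listed because the libraries, or the male-called and female-called cells in them, went opposite ways.

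Cell shares turned direction between ages. The CJ to NC share ratio of B cell-like cells was 5.88 at 5 and 0.550 at 9 months, that of macrophage-like cells 0.811 (0.979 in female-called cells alone) and 1.69, and that of neutrophil-like cells 0.617 and 1.54, the last resting on 87 immature cells. Female-called B cell-like shares were smaller in CJ at both ages. Plasma cell-like cells, under 100 in the 5-month libraries, went from 0.427 (0.248 to 0.733) to 1.75 (1.47 to 2.08), but their female-called shares were larger in CJ at both ages (0.464% against 0.333%, then 5.74% against 3.11%). Female-called and male-called cells went opposite ways for T cell-like shares at 5 months (0.744 and 1.46) and 9 months (1.12 and 0.514), B cell-like (0.143 and 14.6) and conventional dendritic-like shares at 5 months (1.62 and 0.334), and fibroblast-like shares at 9 months (0.590 and 1.30). Acinar-like ratios at 9 months were 0.699 and 1.57 (most cells uncalled). Cluster 31 held most female-called ones, so no direction is read from the 0.699. Neutrophil-like shares at 9 months rose among female-called cells alone (2.66, against 0.901).

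Gene levels did so too. The median log2 fold of digestive enzyme RNA, CJ against NC, was 0.82 at 5 and -1.38 at 9 months in macrophage-like cells and 0.70 and -0.81 in T cell-like cells. Dlk1, a preadipocyte marker, had log2 folds of 0.88 and -2.28 in fibroblast-like cells, the protease gene Prtn3 -0.73 and 2.58 in macrophage-like cells, and the cytokine Il17a 1.68 and -0.93 in T cell-like cells, the last 3 resting on few cells in at least 1 library. Outside the kept cells, barcodes of the 5-month CJ library held 2354 UMIs of the insulin gene Ins2, of which 2299 were in 1 barcode with 415 genes, below the gene minimum. Left-out barcodes of the other libraries held 2, 11 and 11.

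The clock pattern, E-box and D-box genes higher in the CJ libraries, was weighed first. RNA freed from other cells should raise these genes in every class alike. The gap was summed over the list members called higher in macrophage-like cells, which at 9 months were the 5 genes Per2, Per3, Nr1d2, Dbp and Tef. In T cell-like cells it was 4.56% of that in macrophage-like cells (-2.38 to 11.97) at 9 months, the age with the higher bound. This argues against free RNA for these genes, although choosing them by their macrophage-like gap tends to lower the percentage. Against a difference in 1 of the pooled animals, the lowest median over female-called and male-called cells was 0.345 (0.257 to 0.461) for fibroblast-like cells at both ages and macrophage-like cells at 5 months. For macrophage-like cells at 9 months the female-called median was 0.095 (-0.073 to 0.248) against 0.776 in male-called cells, so 1 animal and both cannot be told apart there. Arntl, of opposite phase, had a log2 fold of -1.80 in fibroblast-like cells at 5 months, which a different hour of sampling and a shifted clock under jetlag would both give, so these cannot be told apart without sampling times.

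Uba52, a ubiquitin fusion gene, was higher in the 9-month CJ library in all 8 classes with at least 100 cells in each library, with log2 folds from 1.44 to 1.69. That narrow range goes with a difference of the whole library in capture or in the assignment of reads among near-identical copies, which stays open: Gstp1, also with such copies, had log2 folds from 0.653 (neutrophil-like) to 1.71 (acinar-like). A difference in 1 of the pooled animals is argued against by the lowest fold in female-called or male-called cells at 9 months, 1.31. At 5 months the folds were above 0 in all 8 classes, from 0.086 to 0.401, so a response to jetlag at both ages that is smaller at 5 months stays open. A response at 9 months alone was not tested.

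B cell-like cells of the 5-month CJ library came nearly all from 1 animal: 98.0% (95.9 to 99.2) of 350 sex-called ones were male-called, against 37.0% of all called cells of that library. Naive T cell clusters were also 3.40 times (1.83 to 6.30) as large a share of its male-called as of its female-called cells, against ratios of 0.408, 0.712 and 0.342 in the other libraries. That ratio goes with lymph node tissue dissected with the pancreas of that male, but other values do not add to it. The naive clusters were 18.8% of T cell-like cells there and 18.9% in NC, T cell-like cells 4.07% and 4.36% of all cells, and 30 naive T cells were male-called beside 343 B cells. Lymph node tissue, infiltration of that animal's pancreas by lymphocytes and a response to jetlag in males, which was not tested, all stay open.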

How the results depend on the processing

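Weighting the clusters of a class alike, the cell filters for male-called shares and the other readings of the free-RNA rule were chosen after the results had been seen, and every other alternative before the data were examined. The labels give no replicate numbers to pair by. Pairing CJ with NC by age, or the male-called and female-called sums of a comparison by sex, would leave 1 degree of freedom and was not run. The planned repeats without 1 library were not run, since that empties a group. A value counted as moved when it left the counting interval of the main value, which cell-level depth makes narrow. Of 1812 values of 132 named-gene folds under the alternatives, 1246 stayed within it, 562 moved and 4 that had been called turned direction. Of 4640 values of 336 list medians these numbers were 2957, 1674 and 9, and of 260 values of 33 share ratios 175, 75 and 10. The cause of the changes below was not tested, apart from what the construction of an alternative shows. Across all alternatives run, the E-box and D-box clock medians stayed above 0 in fibroblast-like and macrophage-like cells at both ages, as did the cytokine medians of macrophage-like cells between ages in NC and in CJ. Macrophage-like shares kept their direction in 3 of the 4 comparisons. At 5 months their ratio was 0.979 in female-called cells, with shares whose counting intervals overlap. T cell-like shares kept theirs between ages in NC and in CJ.

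In female-called cells alone, the share ratios were 0.143 (B cell), 0.744 (T cell), 1.08 (acinar), 1.62 (conventional dendritic), 1.05 (fibroblast) and 0.979 (macrophage) for CJ against NC at 5 months and 0.809 (B cell), 1.12 (T cell), 0.699 (acinar) and 1.56 (macrophage) for CJ against NC at 9 months. Those for the other comparisons were 11.3 (B cell), 3.99 (T cell), 1.72 (acinar) and 0.233 (macrophage) for 9 against 5 months in NC and 64.3 (B cell), 6.02 (T cell), 1.11 (acinar), 0.707 (fibroblast) and 0.373 (macrophage) for 9 against 5 months in CJ. There the median log2 folds were 1.11 (CJ against NC, 5 months) for E-box and D-box clock genes in fibroblast-like cells, 0.095 (CJ against NC, 9 months) for E-box and D-box clock genes in macrophage-like cells and 0.30 (CJ against NC, 9 months) for Prc1 in macrophage-like cells. Further values there were 1.05 (ages in NC) and 0.88 (ages in CJ) for myofibroblast genes in fibroblast-like cells, 1.45 (ages in NC) and 0.35 (ages in CJ) for inflammatory cytokines in macrophage-like cells and -0.21 (ages in CJ) for immediate early genes in acinar-like cells. The direction turned for B cell and conventional dendritic shares at 5 months, T cell shares at 9 months, fibroblast shares between CJ ages, Prc1 and, on few cells, the immediate early genes. The fibroblast ratio at 5 months crossed 1 as well, but the counting intervals of its 2 shares overlapped. Most acinar-like cells had no sex call, so acinar ratios among called cells can follow the rate of calls except at 9 months. These are counted in the totals above, and no direction is read from the 2 between ages that turned. Other called shares at 5 months nearly leave acinar-like cells out.

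In male-called cells alone, the share ratios were 14.6 (B cell), 1.46 (T cell) and 0.891 (macrophage) for CJ against NC at 5 months and 0.348 (B cell), 0.514 (T cell), 1.57 (acinar) and 0.901 (neutrophil) for CJ against NC at 9 months. Between ages they were 0.699 (acinar) and 0.433 (macrophage) for 9 against 5 months in NC and 0.369 (B cell), 2.01 (T cell), 0.613 (acinar), 0.830 (macrophage) and 0.889 (mature dendritic) for 9 against 5 months in CJ. For genes the median log2 folds were 1.51 (CJ against NC, 5 months) and 0.80 (CJ against NC, 9 months) for E-box and D-box clock genes in fibroblast-like cells, 0.78 (CJ against NC, 9 months) for E-box and D-box clock genes in macrophage-like cells, -0.47 (CJ against NC, 9 months) for Prtn3 in macrophage-like cells and 0.56 (CJ against NC, 9 months) for Il17a in T cell-like cells. The others there were 1.30 (ages in NC) and 0.94 (ages in CJ) for myofibroblast genes in fibroblast-like cells, 1.17 (ages in NC) and 1.76 (ages in CJ) for inflammatory cytokines in macrophage-like cells, 0.28 (ages in CJ) for Cd163l1 in T cell-like cells and -0.34 (ages in CJ) for proliferation genes in B cell-like cells. B cell shares between CJ ages, Prtn3, Il17a, Cd163l1 and the B cell-like proliferation genes changed direction there. The ratios of neutrophil shares at 9 months and mature dendritic shares between CJ ages crossed 1 as well, but the counting intervals of those shares overlapped.

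With the looser cell filter, the share ratios were 1.13 (T cell) and 1.36 (acinar) for CJ against NC at 5 months and 0.594 (B cell), 0.879 (T cell) and 0.692 (acinar) for CJ against NC at 9 months. For ages they were 6.53 (T cell) and 0.616 (acinar) for 9 against 5 months in NC and 1.47 (B cell), 0.313 (acinar) and 0.784 (macrophage) for 9 against 5 months in CJ. Under the stricter one, the share ratios were 1.48 (acinar) and 0.880 (macrophage) for CJ against NC at 5 months and 0.327 (macrophage) for 9 against 5 months in NC. The CJ ages gave 1.16 (B cell), 4.18 (T cell), 0.358 (acinar) and 0.639 (macrophage) for 9 against 5 months in CJ. The male-called percentage of the 9-month NC library was 47.7% with the stricter filter. Without acinar-like cells in the total, which raises the other shares by construction, the share ratios were 0.943 (macrophage) for CJ against NC at 5 months and 0.316 (macrophage) for 9 against 5 months in NC. To these add 1.05 (B cell), 3.74 (T cell) and 0.569 (macrophage) for 9 against 5 months in CJ. The macrophage-like ratio at 5 months was 0.846 at resolution 0.8 and 0.853 at resolution 2.5.

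A pseudocount of 1 CPM gave medians of 1.38 (CJ against NC, 5 months) and 0.86 (CJ against NC, 9 months) for E-box and D-box clock genes in fibroblast-like cells and 0.55 (CJ against NC, 5 months) and 0.74 (CJ against NC, 9 months) for E-box and D-box clock genes in macrophage-like cells. Besides, it gave 1.24 (ages in NC) and 0.84 (ages in CJ) for myofibroblast genes in fibroblast-like cells and 1.43 (ages in NC) for inflammatory cytokines in macrophage-like cells. With 20 CPM, which draws folds of low genes to 0 by construction, the median log2 folds were 0.78 (CJ against NC, 5 months) and 0.43 (CJ against NC, 9 months) for E-box and D-box clock genes in fibroblast-like cells and 0.14 (CJ against NC, 5 months) and 0.20 (CJ against NC, 9 months) for E-box and D-box clock genes in macrophage-like cells. The rest were 0.83 (ages in NC) and 0.67 (ages in CJ) for myofibroblast genes in fibroblast-like cells and 1.21 (ages in NC) and 1.14 (ages in CJ) for inflammatory cytokines in macrophage-like cells. A minimum of 20 UMIs brought a median of 0.51 (CJ against NC, 5 months) for E-box and D-box clock genes in fibroblast-like cells. Without a minimum above 1 UMI the median log2 folds were 0.51 (CJ against NC, 5 months) for E-box and D-box clock genes in fibroblast-like cells and 1.39 (ages in NC) for inflammatory cytokines in macrophage-like cells. At least 200 UMIs left a median of 0.82 (CJ against NC, 9 months) for E-box and D-box clock genes in fibroblast-like cells. Cells thinned to 3000 UMIs had medians of 0.64 (CJ against NC, 5 months) and 0.68 (CJ against NC, 9 months) for E-box and D-box clock genes in macrophage-like cells and 1.02 (CJ against NC, 9 months) for E-box and D-box clock genes in fibroblast-like cells. Beyond these, thinning gave 0.89 (ages in NC) and 0.89 (ages in CJ) for myofibroblast genes in fibroblast-like cells and 1.48 (ages in NC) and 1.53 (ages in CJ) for inflammatory cytokines in macrophage-like cells. TMM factors gave medians of 1.504 (ages in NC) and 1.16 (ages in CJ) for inflammatory cytokines in macrophage-like cells. Class medians set to 0 gave a median of 1.47 (ages in NC) for inflammatory cytokines in macrophage-like cells. With called doublets kept, the median log2 folds were 1.10 (CJ against NC, 5 months) for E-box and D-box clock genes in fibroblast-like cells and 0.85 (ages in CJ) for myofibroblast genes in fibroblast-like cells. Also moved were -0.38 (ages in CJ) for antigen-presenting fibroblast genes in fibroblast-like cells and 1.25 (ages in CJ) for inflammatory cytokines in macrophage-like cells. The antigen-presenting fibroblast genes alone changed sign there.

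With clusters weighted alike, the median log2 folds were 0.59 (CJ against NC, 5 months) and 0.68 (CJ against NC, 9 months) for E-box and D-box clock genes in macrophage-like cells, 0.15 (ages in NC) and -0.006 (ages in CJ) for myofibroblast genes in fibroblast-like cells, 0.79 (ages in NC) and 0.71 (ages in CJ) for inflammatory cytokines in macrophage-like cells and 0.21 (ages in NC) and 0.094 (ages in CJ) for type 17 genes in T cell-like cells. The remaining medians were 0.33 (ages in NC) for proliferation genes in B cell-like cells, -0.017 (ages in CJ) for MHC class I in acinar-like cells and 0.075 (ages in CJ) for proliferation genes in T cell-like cells. Of these, the type 17, MHC class I and proliferation medians, and the myofibroblast median between CJ ages, changed sign. Clusters come from the same expression values, so the cause stays open. Of the 144 gene names, 67 were shared with a free-RNA factor of 3 and 52 with no such rule.

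In simulated data at the real depth, genes changed 2-fold in acinar-like cells were called in 16.4% of cases at 5 months and 32.8% at 9 months, against 69.4% and 63.5% in fibroblast-like cells. The pseudocount shrinks folds of low genes by construction: a 4-fold change had a median size on the log2 scale of 0.641 in acinar-like and 1.54 in fibroblast-like cells at 5 months. Ductal-like and tuft-like cells were too few for gene levels. No interval here covers differences between animals.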

Other observations

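Cirbp was lower and Hspa8 higher in the CJ libraries, not always past 1.5-fold. The genes of this paragraph were chosen after their values had been seen. Cirbp (ENSMUSG00000045193), a cold-inducible RNA-binding protein, was lower in CJ in each of 5 classes, with log2 folds at 5 and 9 months of -1.15 and -1.02 in fibroblast-like, -1.04 and -0.73 in macrophage-like, -0.47 and -0.64 in acinar-like, -0.87 and -0.46 in T cell-like and -0.26 and -0.47 in B cell-like cells. Hspa8 (ENSMUSG00000015656), a constitutive member of the heat shock family, was higher in CJ in the same classes, with 1.05 and 0.61, 0.86 and 0.37, 1.19 and 0.81, 0.88 and 0.21, and 0.48 and 0.33. Rbm3, another cold-inducible RNA-binding protein, did not follow Cirbp in each class: its log2 folds were 0.01 and -0.08 in fibroblast-like, -0.31 and -0.40 in macrophage-like, 0.15 and 0.04 in acinar-like, -0.72 and -0.47 in T cell-like and -1.18 and -0.23 in B cell-like cells. The cause was not tested, and the hour of sampling is not in the labels.

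Neutrophil-like cells of the 9-month CJ library were of 2 kinds. A cluster of mature neutrophil-like cells held 98.7%, 100%, 95.6% and 60.3% of the class in NC and CJ at 5 and NC and CJ at 9 months. The others, 2, 0, 7 and 87 cells, formed a cluster of immature cells with granule protein genes such as Ngp, Camp and Ltf. Of the 87, 64 were female-called and 4 male-called. Without that cluster the 9-month shares of the class were 1.34% (CJ) and 1.37% (NC). NK cell-like cells numbered 57, 61, 54 and 61 in the same order. Endocrine-like cells numbered 5, 4, 12 and 16, too few for gene levels.

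The gene model Gm10076, chosen after its values had been seen, moved with Uba52: its log2 folds, CJ against NC at 9 months, were 1.43 in fibroblast-like, 1.35 in macrophage-like, 1.51 in acinar-like, 1.47 in T cell-like and 1.62 in B cell-like cells, and between 0.29 (acinar-like) and 0.45 (macrophage-like) at 5 months. No further test of this pair was run.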
